A study of Mus musculus with 30 samples.

How the data were processed

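RNA sequencing counts of sorted mouse bone marrow progenitors were compared between mice given MTP10-HDL and mice given phosphate-buffered saline (PBS). MTP10-HDL is a high-density lipoprotein nanoparticle that carries a muramyl tripeptide, a fragment of the bacterial cell wall sensed through Nod2. Hematopoietic stem cells (HSCs) gave 7 PBS and 6 MTP10-HDL samples, and multipotent progenitors (MPPs) gave 2 PBS and 3 MTP10-HDL samples. Per the labels, the cells came from C57BL/6 mice and each RNA sample is a pool of 4 mice, so every p-value measures the spread between such pools and not between single mice. The labels give the treatment in full for the MPP samples, with 3 injections over 5 days and the mice killed on the day after the last one. The same schedule is not given for the HSC samples in the sources used here. The series also holds 12 ATAC-seq samples, 3 per group and each a pool of 6 mice, which were not analysed here.

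The authors deposited a table of raw read counts per Ensembl gene for each cell type, with 55471 genes, 13 HSC columns and 5 MPP columns. All values were whole numbers, no pair of columns within a table was identical, and no column was left out. Per the labels' protocols, HSC libraries were made from amplified complementary DNA and sequenced as single 50-base reads, whereas MPP libraries were poly-A selected, carried insect RNA as carrier and were directional. Per the submitters' processing notes, HSC reads went through CASAVA 1.8.2 and STAR 2.5.2b, and MPP reads through STAR 2.7.2a with DESeq2 1.24 in R 3.6.1, both on the mm10 mouse genome. The counting tool, annotation release, handling of reads with several matches and strand setting are not given in the sources used here. HSC columns carry an unexplained ESC prefix, and the labels number 1 PBS sample 8 while the HSC table holds PBS columns 1 to 7. PBS columns were therefore used as a group, under the table's own numbers, and MPP PBS libraries are numbered 2 and 3. Gene positions on mm10 came from a RefSeq table of assembly GRCm38.p6, matched by symbol. Of the Ensembl identifiers, 55144 were found in a separate name table and 53438 carried the same symbol there.

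Each cell type was fitted apart in R 4.3.3 with edgeR 4.0.16. Counts were scaled by the trimmed mean of M values (TMM), genes with few counts were removed by filterByExpr with its default settings, and treatment was tested by the quasi-likelihood F test. Benjamini-Hochberg adjustment ran over all genes tested, with a false discovery rate (FDR) threshold of 0.05. Expression levels are CPM (counts scaled to a common library total) after TMM scaling, and list scores are means of log2 CPM with a prior count of 2, centred per gene over the libraries of a cell type. Fold changes are MTP10-HDL over PBS throughout. A joint fit with 4 group means tested whether the MPP response differed from the HSC response. Fold changes of both cell types were also correlated across genes, against regrouped libraries, since genes are not independent replicates.

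The main test, the samples in each comparison, the 33 gene lists, the rule for naming genes and a set of alternatives were fixed before the data were examined. The lists cover lineage programs (HSC identity, myeloid priming, lymphoid priming, megakaryocyte-erythroid priming), proliferation (S phase, mitosis, quiescence), metabolism (glycolysis, cholesterol synthesis, oxidative phosphorylation, tricarboxylic acid cycle), immune signalling (interferon response, NF-kB and inflammation, pattern recognition and cytokine receptors, major histocompatibility complex (MHC) class I and class II, adhesion and homing), protein and stress programs (ribosome biogenesis and MYC targets, unfolded protein response, heat shock), signs of RNA quality and sample handling (ribosomal proteins, immediate early genes, replication histones, mitochondrially encoded genes), and markers of other cells that a sort could hold (mature neutrophils, monocytes and macrophages, B cells, T and NK cells, erythroblasts, platelets and megakaryocytes, basophils and mast cells, dendritic cells, stroma and endothelium). Some genes belong to more than 1 list. Each list was tested with camera at its preset correlation of 0.01, adjusted over the 33 lists. Camera was run again with a correlation estimated per list, and the score of each list was compared between groups by a 2-sided exact permutation of the libraries. That score test was added after the data were seen.

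Genes are named by rule. Among genes past the FDR threshold with a mean of at least 10 CPM and an established symbol, the rule took the 10 largest and the 10 smallest fold changes. If fewer than 5 genes passed in a direction, it took the 10 smallest p-values of that direction instead, given as values that did not pass. From each list it took up to 4 members past the threshold, or, for a list past camera with no such member, the 2 members of smallest p. Nod2, Ripk2, Procr, Mpo, Flt3, Gata1, Mki67, Cdk1, Hk2, Il1r1, Csf2rb, Cebpa and Spi1 were always given. Results of a few other genes that the rule takes are not reported here. No single gene passed in either cell type, so all gene values are values below the threshold.

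Alternatives fixed in advance were DESeq2 1.42.0 and limma 3.58.1 voom with sample quality weights in place of edgeR, DESeq2 size factors in place of TMM, no filter or a filter at a mean of 10 CPM, replicate number as a block, a joint fit of both cell types, an FDR threshold of 0.1 and each library left out in turn. Added after the data were seen were fits without HSC PBS 5 and 7, which had the highest background of olfactory and vomeronasal receptor reads, and without HSC PBS 1 and MTP10-HDL 1, which had the highest monocyte and macrophage scores. Also added were a technical group term, an immunoglobulin share covariate, removal of immunoglobulin genes before scaling, and MPP counts thinned to the smallest MPP library. HSC technical groups were set by library quality alone: 4 libraries with under 28000 genes detected, 4 others with more than 0.8% of counts in ribosomal RNA, and the other 5. Groups below 10 libraries were compared by exact permutation, with 1716 arrangements in HSCs, where the smallest possible p is 0.000583, and 10 in MPPs, where it is 0.1. Folds against a group with no reads used a floor of 3 counts, and such bounds, like the Wilson intervals of shares, cover counting error only. Random draws used seed 11.

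The pipeline was tested on simulated data shaped like each table, with 100 genes planted at each of 2 effect sizes. At log2 changes of 2, edgeR recovered 95% of planted genes in the HSC design and 86% in the MPP design. At log2 changes of 1 it recovered 42% and 10%. False calls numbered 1 for edgeR and 24 for DESeq2 in the HSC design, and 13 and 51 in the MPP design. A planted list was called in both designs, and 0 of 32 lists without a planted effect were. Simulated genes vary independently, unlike real ones: over regrouped HSC libraries camera called a median of 14 lists and at least 4. HSC libraries held 4064155 to 7879858 counts and MPP libraries 11252479 to 32769369.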

Results

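Transcript counts were compared in 2 sorted bone marrow populations of C57BL/6 mice, stem cells (HSCs) and the multipotent progenitors (MPPs) they give rise to, to ask how each responds to MTP10-HDL, a nanoparticle designed to induce trained innate immunity through Nod2. HSC libraries numbered 7 with PBS and 6 with MTP10-HDL and held 5922378 ± 1427042 (SD) and 6582597 ± 963670 counts (exact permutation p = 0.368). MPP PBS libraries 2 and 3 held 14691375 and 11252479 counts. The MPP MTP10-HDL libraries 1, 2 and 3 were deeper, with 32769369, 30506148 and 17555267 counts. Kits differed between the cell types, so levels are compared within a cell type only. Mitochondrial ribosomal RNA took 24.0% of HSC PBS counts and 0.119% of MPP PBS counts.

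Within the HSC table, libraries also differed in ways that the treatment does not explain. PBS 1 and 4 and MTP10-HDL 2 and 3 held 24233 to 27528 detected genes, fewer than any other HSC library. PBS 2 and 3 and MTP10-HDL 1 and 4 carried the highest ribosomal RNA shares, 0.813% to 1.26%. Both treatments fall in each of these technical groups and in the third, which holds the other 5 libraries, so differences could be computed within them. Immunoglobulin genes took 5.31% ± 6.97 (SD, n = 7) of counts in PBS HSCs, from 0.271% in PBS 6 (95% Wilson interval 0.267% to 0.275%) to 19.8% in PBS 2 (19.81% to 19.88%), and 1.81% ± 1.63 (n = 6) in MTP10-HDL HSCs (exact permutation p = 0.28). In MPPs their share was 9.35% ± 4.46 (n = 2) with PBS and 3.75% ± 0.862 (n = 3) with MTP10-HDL, and the exact p of 0.1 is the smallest that 10 arrangements allow. Ribosomal RNA shares parted the MPP treatments as fully, at 1.36% ± 0.153 with PBS and 0.759% ± 0.22 with MTP10-HDL, and so did the share of the 10 most abundant genes, 11.8% ± 3.19 and 7.80% ± 0.248 (exact p = 0.1 for each). MPP differences by treatment therefore go along with differences in library quality.

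HSCs from MTP10-HDL mice carried more transcripts of the interferon response, the antiviral program that type I interferon induces. All 35 measured members of this list were higher, with a median log2 fold change of 0.66. Dhx58 (ENSMUSG00000017830, mm10 chromosome 11, 100694884 to 100704271), which encodes the RNA-sensing helicase LGP2, was at 15.6 ± 2.57 CPM (SD, n = 7) with PBS and 31.1 ± 8.74 CPM (n = 6) with MTP10-HDL, a log2 fold change of 1.00 (SE 0.20). Ifi44, an interferon-induced gene on chromosome 3 (151730922 to 151749910), went from 38.4 ± 7.00 CPM to 71.5 ± 20.5 CPM (log2 fold change 0.89, SE 0.18). Oas1a, a sensor of double-stranded RNA, had a log2 fold change of 1.11 (SE 0.25), Parp12, which is not on the list, 0.76 (SE 0.17) and Irf9, the DNA-binding subunit of the interferon-activated factor ISGF3, 0.71 (SE 0.15). All 6 treated libraries lay above the PBS median for each of these 5 genes, which were themselves chosen by smallest p in these libraries. The list rose as a whole (camera adjusted p = 4.19e-25, and adjusted p = 0.0671 with an estimated correlation). Of its members 23 were higher at an unadjusted p under 0.05 and 19 passed when adjusted over the list alone. Its score was -0.30 ± 0.13 (SD, n = 7) with PBS and 0.35 ± 0.44 (n = 6) with MTP10-HDL, with all 6 treated libraries above every PBS library (exact permutation p = 0.000583, the smallest possible, and Benjamini-Hochberg over the lists 0.0192). Within the technical groups the score differed by 0.62, 0.67 and 0.62 (stratified exact p = 0.00278, the smallest of 360 arrangements). MTP10-HDL 1 had the highest interferon score, 1.13, and also the highest monocyte and macrophage score, 2.48. Without it the difference fell from 0.66 to 0.50 (exact p = 0.00126).

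No single HSC gene passed the FDR threshold in edgeR. Among 16631 genes tested, 1469 had an unadjusted p under 0.05 (725 higher, 744 lower), against 832 by chance. limma voom called 0 genes, and DESeq2 called 104 (26 higher, 78 lower), among them Tox and Ermap (adjusted p = 8.5e-05 for each) as well as Dhx58 (0.00318). With no filter on low counts edgeR called 44 genes (7 higher, 37 lower). The median log2 fold change of all genes was -0.02, against -0.15 without the filter and -0.23 in DESeq2. Without MTP10-HDL 4 edgeR called 1 gene, Ermap (log2 fold change -2.11, adjusted p = 0.0230). At the level of lists, 19 of 33 passed camera, 12 up and 7 down, against a median of 14 over regroupings of the same libraries. With an estimated correlation 1 passed, the erythroblast markers, and by the exact score test 3 passed after adjustment: interferon response, glycolysis and erythroblast markers. Since no gene passed, every list member named is a value below the threshold over all genes.

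**Figure D1:**
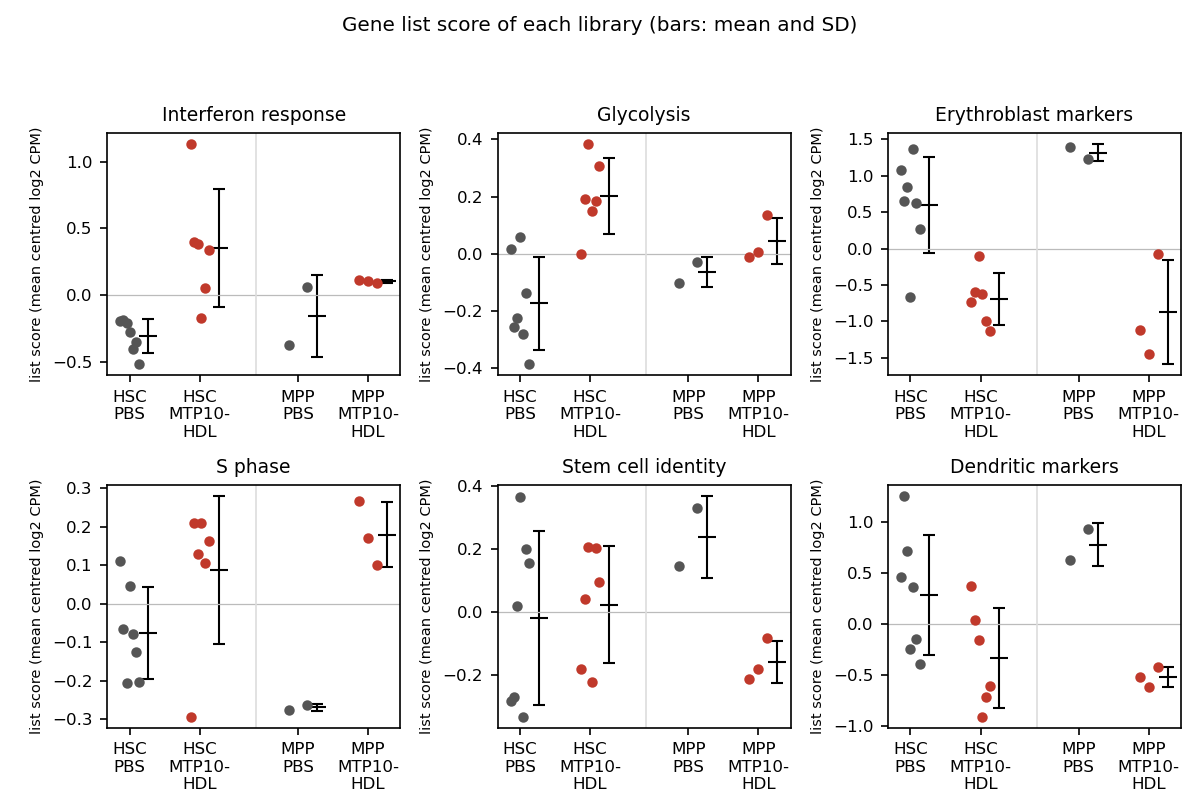
Score of 6 gene lists (mean centred log2 CPM) in each library, by cell type and treatment; dots are libraries, bars the mean and SD. In HSCs all 6 MTP10-HDL libraries lie above every PBS library for the interferon response. In MPPs all 3 MTP10-HDL libraries lie outside the range of both PBS libraries for all 6 lists. They lie above for the interferon response, glycolysis and S phase, and below for erythroblast markers, stem cell identity and dendritic markers.

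Genes of glycolysis also rose in HSCs. Of 20 measured, 18 were higher and 11 of these had an unadjusted p under 0.05, with a median log2 fold change of 0.43 (camera adjusted p = 1.64e-08, and 0.0671 as adjusted p with an estimated correlation). Adjusted over the list alone, 7 passed. Pkm (chromosome 9, 59656576 to 59679372), which encodes pyruvate kinase, was at 104 ± 18.1 CPM with PBS and 150 ± 18.2 CPM with MTP10-HDL (log2 fold change 0.53, SE 0.13), and Eno1, an enolase, was higher by 0.56 (SE 0.15). G6pdx, which opens the pentose phosphate pathway and is not on the list, was among the 10 named higher genes of smallest p (log2 fold change 0.73, SE 0.17), with 100.5 ± 18.4 CPM (n = 7) and 167 ± 41.5 CPM (n = 6). The glycolysis score was higher by 0.38 (exact p = 0.0035, Benjamini-Hochberg 0.0385) and by 0.25, 0.31 and 0.52 within the technical groups.

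Genes for mitochondrial respiration and DNA replication were also higher in HSCs, with smaller medians than glycolysis, and so were ribosomal protein genes, a list that stands for RNA quality. Oxidative phosphorylation genes rose (46 of 52 higher, 8 at p under 0.05 and 2 adjusted over the list alone; median 0.20; camera adjusted p = 2.07e-07, and adjusted p = 0.39 with an estimated correlation), led by the ATP synthase subunit Atp5b (0.52, SE 0.13) and the complex I subunit Ndufv1 (0.52, SE 0.14). Their median was 0.37 without PBS 1 and 0.085 without PBS 5 and 7 together, and their scores differed by -0.0043, 0.16 and 0.50 within the technical groups. In the tricarboxylic acid cycle 18 of 22 genes were higher, 5 at p under 0.05 and 0 adjusted over the list alone, with Ogdh at 0.42 (SE 0.13). That list rose (median 0.16, adjusted p = 0.000647, and adjusted p = 0.389 with an estimated correlation), although without PBS 5 and 7 the call ended (0.086, adjusted p = 0.076). S phase genes rose with 24 of 29 higher, 6 at p under 0.05 and 0 adjusted over the list alone (median 0.18, adjusted p = 0.000586, and adjusted p = 0.389 with an estimated correlation). Among them Chaf1b, a chromatin assembly subunit, was higher by 0.54 (SE 0.17) and the DNA ligase Lig1 by 0.42 (SE 0.16). Ribosomal protein genes rose with 38 of 46 higher, 2 at p under 0.05 and 0 adjusted over the list alone (median 0.16, adjusted p = 0.000647, and adjusted p = 0.623 with an estimated correlation). Examples are Rpl5 (0.53, SE 0.21) and Rpl4 (0.40, SE 0.18). This call ended without PBS 5 (median 0.092, adjusted p = 0.0723), the median was 0.25 without PBS 1, and within the technical groups the scores differed by -0.14, -0.02 and 0.54.

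Erythroid transcripts were lower in HSCs given MTP10-HDL. All 15 erythroblast markers were lower, with a median log2 fold change of -1.32. Ermap (ENSMUSG00000028644, chromosome 4, 119175457 to 119190013), an erythroid membrane protein, was at 129 ± 41.3 CPM (SD, n = 7) with PBS and 37.6 ± 21.99 CPM (n = 6) with MTP10-HDL, a log2 fold change of -1.77 (SE 0.32). The erythroblast list fell (camera adjusted p = 2.18e-17, and adjusted p = 0.046 with an estimated correlation). Of its members 11 were lower at p under 0.05 and 9 passed adjusted over the list alone. Its score went from 0.60 ± 0.66 to -0.70 ± 0.36, a difference of -1.29 (exact p = 0.0035, Benjamini-Hochberg 0.0385), and differed by -0.56, -1.42 and -1.82 within the technical groups (stratified exact p = 0.0111). Genes of megakaryocyte-erythroid priming fell too (16 of 22 lower, 10 at p under 0.05, 9 adjusted over the list alone; median -0.37; camera adjusted p = 4.33e-08, and adjusted p = 0.183 with an estimated correlation), Ermap and the cytoskeletal gene Add2 (-1.85, SE 0.37) among them. Their median was -0.68 without MTP10-HDL 3 and -0.23 without PBS 1, and their score differed by -0.56 (exact p = 0.00816, Benjamini-Hochberg 0.0673), or by -0.52, -0.50 and -0.68 within the technical groups. The erythroid transcription factor Gata1 was lower by only 0.25 on the log2 scale (log2 fold change -0.25, SE 0.33).

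Markers of B cells, dendritic cells and basophils fell as well, together with lymphoid priming genes. All 14 B cell markers were lower, 9 at p under 0.05 and 2 adjusted over the list alone (median -1.60, camera adjusted p = 3.22e-07, and adjusted p = 0.183 with an estimated correlation). They include Fcrla (log2 fold change -1.78, SE 0.50). Without PBS 2, the library with 19.8% immunoglobulin counts, the B cell median was -0.92, and the immunoglobulin share itself differed by -1.16, -2.64 and 0.37 (log2) within the technical groups. Lymphoid priming genes fell with 18 of 23 lower, 10 at p under 0.05 and 0 adjusted over the list alone, against 1 higher at p under 0.05 (median -0.54, adjusted p = 0.00068, and adjusted p = 0.389 with an estimated correlation). The chemokine receptor gene Ccr9 was lower (-1.21, SE 0.38), as was Rag1 (-2.93, SE 0.96), which encodes the antigen receptor recombinase and was at 9.81 ± 17.97 CPM in PBS. PBS 5 held 50.3 CPM of Rag1, and without it the log2 fold change was -1.25. The lymphoid scores differed by 0.17, -0.93 and -0.70 within the technical groups. Dendritic cell markers fell with 9 of 11 lower, 3 at p under 0.05 and 2 adjusted over the list alone, against 1 higher at p under 0.05 (median -0.97, adjusted p = 0.000346, and adjusted p = 0.183 with an estimated correlation), Zbtb46, a transcription factor of conventional dendritic cells, by -1.22 (SE 0.34). Without PBS 2 their median was -0.57. Basophil and mast cell markers fell with 6 of 7 lower, 4 at p under 0.05 and 3 adjusted over the list alone (median -0.78, adjusted p = 0.00157, and adjusted p = 0.183 with an estimated correlation). Ms4a2, the beta chain of the high-affinity IgE receptor, was at 25.0 ± 13.4 CPM and 5.31 ± 5.47 CPM (-2.25, SE 0.58), and the mast cell protease gene Mcpt8 was lower by 1.28 (log2 fold change -1.28, SE 0.43).

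Several myeloid and immune lists rose in HSCs by camera, but none of these passed the exact score test after adjustment. The exact permutation p of the score was 0.245 for myeloid priming, 0.149 for mature neutrophil markers, 0.508 for receptors, 0.0245 for MHC class I and 0.230 for adhesion and homing. Neutrophil markers stand for other cells that a sort could hold, and their part in the myeloid priming values was not tested. Myeloid priming genes were higher in 20 of 25 cases, 2 at p under 0.05 and 0 adjusted over the list alone (median 0.40, camera adjusted p = 0.000647, and adjusted p = 0.427 with an estimated correlation). Csf3r, the receptor of G-CSF, was at 0.40 (SE 0.17) and Plac8 at 0.50 (SE 0.23). Their median was 0.25 without MTP10-HDL 1 and 0.11 without MTP10-HDL 4. Mature neutrophil markers were higher for 17 of 17 genes, none at p under 0.05 or adjusted over the list alone, with Chil3 at 1.12 (SE 0.61) and Cxcr2 at 0.87 (SE 0.53). This list rose (median 0.87, adjusted p = 4.31e-07, and adjusted p = 0.389 with an estimated correlation), with a median of 0.33 without MTP10-HDL 1 and 1.38 without PBS 5. Pattern recognition and cytokine receptor genes rose (27 of 35 higher, 7 at p under 0.05, against 1 lower; 1 adjusted over the list alone; median 0.31; adjusted p = 0.00233, and adjusted p = 0.538 with an estimated correlation). They included Myd88, the adaptor of Toll-like and interleukin-1 receptors (11.7 ± 3.401 and 22.6 ± 3.18 CPM; 0.95, SE 0.21), and the interferon receptor gene Ifnar1 (0.50, SE 0.16). Without MTP10-HDL 1 this call ended (median 0.036, adjusted p = 0.374). Among MHC class I genes 16 of 16 were higher, 4 at p under 0.05 and 0 adjusted over the list alone. The peptide transporter Tap1 was higher by 0.50 (SE 0.16) and H2-D1 by 0.37 (SE 0.13). MHC class I rose (median 0.35, adjusted p = 9.28e-06, and adjusted p = 0.183 with an estimated correlation), with a median of 0.21 without PBS 5 and 7. Adhesion and homing genes rose with 14 of 20 higher, 4 at p under 0.05 and 1 adjusted over the list alone (median 0.17, adjusted p = 0.00233, and adjusted p = 0.183 with an estimated correlation; 0.11 without MTP10-HDL 1). P-selectin (Selp) was at 1.07 (SE 0.28) and Cxcr4, the receptor that holds stem cells in the marrow, at 0.54 (SE 0.18).

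Immediate early genes, which respond within minutes to stress and growth factors, fell in HSCs. Their list and those of replication histones and ribosomal proteins were fixed in advance as signs of RNA quality and sample handling, and all 3 moved with treatment here, so they are not read as a response. Of 22 measured, 20 were lower, 11 at p under 0.05 and 0 adjusted over the list alone (median -1.07, camera adjusted p = 8.72e-07, and adjusted p = 0.389 with an estimated correlation). Egr1 was at 212 ± 189 CPM (n = 7) and 59.9 ± 24.3 CPM (n = 6; log2 fold change -1.83, SE 0.58), and Jund was lower by 1.62 (log2 fold change -1.62, SE 0.52). Immediate early scores differed by -1.14, -1.78 and 0.25 within the technical groups. Replication histone genes rose with 14 of 16 higher, none at p under 0.05 or adjusted over the list alone (median 0.29, adjusted p = 0.0299, and adjusted p = 0.668 with an estimated correlation). The 2 of smallest p were H1f4 (0.46, SE 0.28) and H2bc4 (-0.75, SE 0.42). This call ended without any of MTP10-HDL 2, 3 and 6 and PBS 3, 5 and 7, with medians of 0.15 to 0.21 and adjusted p from 0.0638 to 0.594. It ended too with replicate number as a block (0.14, adjusted p = 0.599) and among genes of at least 10 CPM (0.22, adjusted p = 0.147).

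Among the 20 named genes of smallest p in HSCs, 14 belong to none of the lists called: Parp12 and G6pdx, given above, and the 12 that follow. Tox (ENSMUSG00000041272, chromosome 4, 6686353 to 6991557), a chromatin factor of lymphoid development, had the smallest p, with 38.5 ± 15.02 CPM and 13.7 ± 2.503 CPM (log2 fold change -1.49, SE 0.25, adjusted p = 0.19). Nfia (-0.86, SE 0.16), a transcription factor of erythroid fate, the mannose 6-phosphate receptor gene Igf2r (-1.01, SE 0.20) and the asparagine synthetase gene Asns (-0.88, SE 0.19) were also lower. So were Paqr9 (-1.92, SE 0.39), Nxpe2 (-1.47, SE 0.31), Slc22a23 (-1.09, SE 0.21) and Zrsr1 (-0.94, SE 0.19). Higher values were found for the small GTPase gene Rhog (0.80, SE 0.16), Traf7 (0.77, SE 0.17), Saal1 (0.71, SE 0.16) and Slc35c1 (0.55, SE 0.12). All 6 treated libraries lay on the same side of the PBS median for each of these 12 genes. As they were chosen by smallest p in the same libraries, this adds no support.

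**Figure D2:**
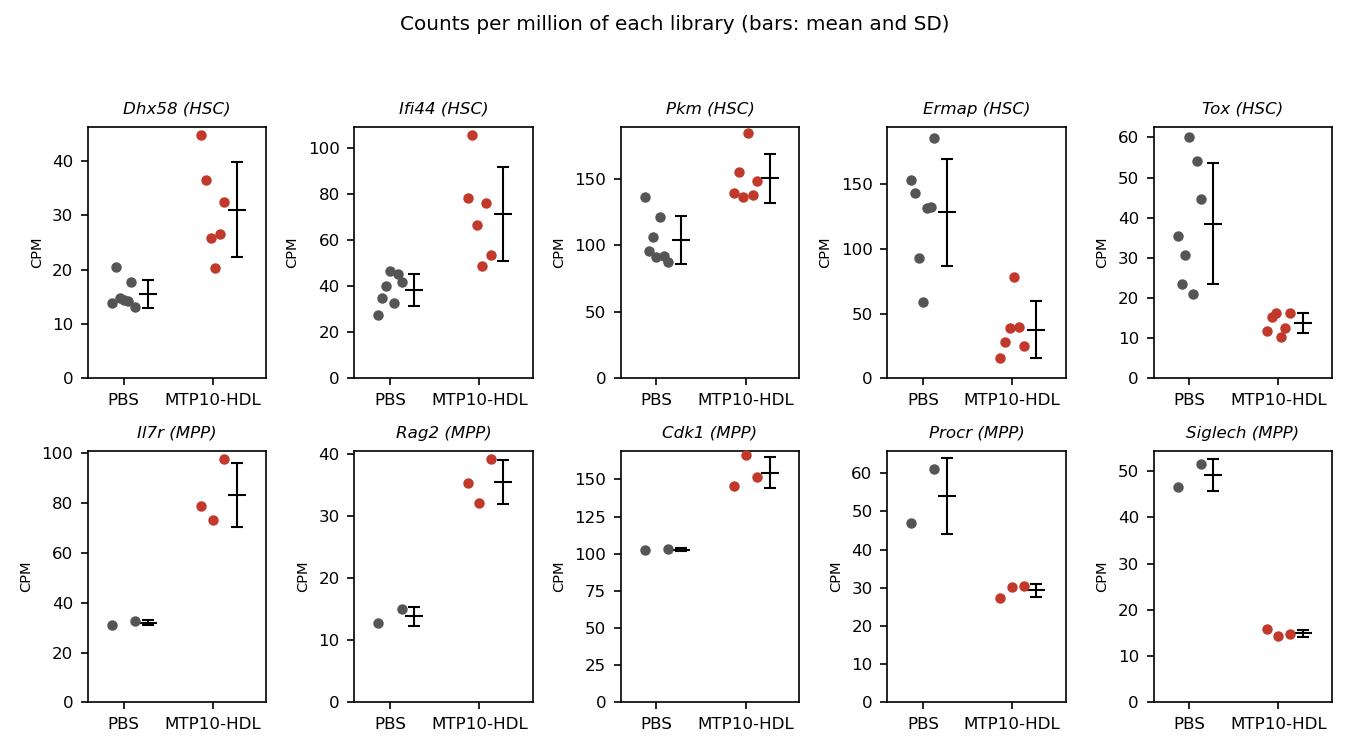
CPM of each library for 5 genes in HSCs (top) and 5 in MPPs (bottom), by treatment; dots are libraries, bars the mean and SD. For all 5 MPP genes the 3 MTP10-HDL libraries lie outside the range of both PBS libraries, and in HSCs the 6 MTP10-HDL libraries lie below every PBS library for Tox.

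HSC identity genes were not called (10 of 25 higher, median -0.03, mean 0.0087, camera upward, adjusted p = 0.683), although with no filter on low counts they were called upward (median 0.026, adjusted p = 0.0308). Procr, a surface marker of stem cells, was at 22.2 ± 3.28 and 22.1 ± 3.53 CPM. No call was made for mitosis (median 0.02, mean -0.0073, camera downward, adjusted p = 0.903), quiescence (0.02, mean -0.16, camera upward, 0.984) or ribosome biogenesis and MYC targets (-0.06, 0.737). Cholesterol synthesis (-0.16, adjusted p = 0.984), NF-kB and inflammation (-0.09, 0.433), heat shock (-0.03, 0.984) and the unfolded protein response (-0.27, 0.139) were not called either. Nor were MHC class II (0.75, adjusted p = 0.244), monocyte and macrophage markers (median -0.03, mean 0.03, camera downward, 0.984), T and NK cell markers (-0.19, 0.249), platelet and megakaryocyte markers (median 0.06, mean -0.21, camera downward, 0.783), stroma and endothelium (-0.61, 0.303) or mitochondrially encoded genes (-0.22, 0.252). Leaving out MTP10-HDL 1 brought calls for mitosis (0.14, adjusted p = 0.0190), NF-kB (-0.19, 0.0262) and monocyte markers (-1.26, 0.00281). MHC class II was called without MTP10-HDL 4 (0.85, 0.0463), and the unfolded protein response without any of MTP10-HDL 2 and 4 and PBS 5, 6 and 7 (-0.32 to -0.42, adjusted p from 0.00494 to 0.0451). Calls came also with replicate number as a block, for monocyte markers (-0.37, adjusted p = 2.32e-06) and the unfolded protein response (-0.27, 0.00429). With no filter MHC class II was called (0.80, 0.0125), and among genes of at least 10 CPM the unfolded protein response was (-0.26, 0.0317). The muramyl peptide receptor gene Nod2 was low in HSCs, with 2.84 ± 1.096 CPM and 3.55 ± 1.94 CPM (log2 fold change 0.31, SE 0.48), and its kinase Ripk2 stood at -0.29 (SE 0.31). Csf2rb, the shared beta chain of the GM-CSF receptor, was at 0.68 (SE 0.29), Mpo at 0.51 (SE 0.35; 0.021 without MTP10-HDL 4), Spi1 at 0.43 (SE 0.21) and Hk2 at 0.24 (SE 0.17). Smaller values were found for Cebpa (0.18, SE 0.39), Cdk1 (0.16, SE 0.17), Flt3 (0.02, SE 0.20), Mki67 (-0.22, SE 0.13) and Il1r1 (-0.25, SE 0.20).

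MPPs given MTP10-HDL carried more S phase and mitosis transcripts. All 30 S phase genes were higher (11 at p under 0.05, 0 adjusted over the list alone), with a median log2 fold change of 0.44. All 30 mitosis genes were higher too (5 at p under 0.05, 0 adjusted over the list alone; median 0.37). Lig1 was higher by 0.64 (SE 0.21). Cdk1, the kinase that starts mitosis, was at 103 ± 0.765 CPM (SD, n = 2) with PBS and 155 ± 10.5 CPM (n = 3) with MTP10-HDL (log2 fold change 0.59, SE 0.19), and Ndc80, a kinetochore gene, was higher by 0.63 (SE 0.20), whereas Mki67 stood at 0.30 (SE 0.34). Both lists rose, S phase with a camera adjusted p = 1.2e-11 and mitosis with 4.35e-08, while the adjusted p with an estimated correlation was 0.143 and 0.215. Scores of all 3 treated libraries lay above both PBS libraries for each list (exact p = 0.1, the smallest possible). Full separation of the treatments is not particular to these lists. It was found for many others, some of them not called, such as glycolysis and the unfolded protein response. Replication histones were not called (5 of 12 higher, median -0.07, adjusted p = 0.621). They were called downward without MTP10-HDL 2, at -1.09 with adjusted p = 0.0238. MPP libraries were poly-A selected and the list was fixed as a sign of RNA quality, so it decides nothing about S phase and mitosis.

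Stem cell genes were lower in MPPs and lymphoid priming genes slightly higher. Of 25 HSC identity genes 20 were lower, 5 at p under 0.05 and 4 adjusted over the list alone, against 1 higher at p under 0.05 (median -0.37, camera adjusted p = 1.43e-05, and adjusted p = 0.143 with an estimated correlation). Procr (chromosome 2, 155751125 to 155755478) was at 54.1 ± 9.99 CPM (n = 2) and 29.3 ± 1.75 CPM (n = 3; log2 fold change -0.88, SE 0.21), and Trpc6 was lower by 1.58 (log2 fold change -1.58, SE 0.31). Il7r (ENSMUSG00000003882, chromosome 15, 9506159 to 9529941), the interleukin-7 receptor needed for lymphoid development, had the smallest p of the higher genes with a mean of at least 10 CPM. It was at 31.95 ± 1.11 CPM and 83.2 ± 12.8 CPM (1.38, SE 0.22, adjusted p = 0.226). Rag2 (chromosome 2, 101624712 to 101632528), a subunit of the antigen receptor recombinase, was at 13.8 ± 1.58 and 35.5 ± 3.59 CPM (1.36, SE 0.23). The lymphoid priming list rose by a small median (0.13; 16 of 23 higher, 6 higher and 4 lower at p under 0.05, 6 and 3 adjusted over the list alone; camera adjusted p = 0.00471, and adjusted p = 0.357 with an estimated correlation). Its call ended without MTP10-HDL 3 (median 0.0017, adjusted p = 0.083) or PBS 3 (0.14, adjusted p = 0.137), and its median was 0.27 without MTP10-HDL 1 and 0.29 without MTP10-HDL 2. Other higher genes of smallest p were Fkbp5, a glucocorticoid-induced chaperone (1.14, SE 0.23), Cst7 (1.47, SE 0.30), Atp8b4 (1.32, SE 0.27), Dtx4 (1.23, SE 0.25), Milr1 (1.20, SE 0.21), Tespa1 (0.98, SE 0.21) and Cd244a (0.92, SE 0.20). None of these higher genes passed over all genes in edgeR, whereas DESeq2 called Il7r (adjusted p = 0.000197) and Rag2 (0.00195), and voom Il7r (0.0425).

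Dendritic, erythroid, megakaryocyte and stromal transcripts were lower in MPPs. The plasmacytoid dendritic cell gene Siglech (ENSMUSG00000051504, chromosome 7, 55768154 to 55779448) was at 49.1 ± 3.46 CPM (n = 2) and 14.97 ± 0.766 CPM (n = 3), a log2 fold change of -1.71 (SE 0.20, adjusted p = 0.0928). Dendritic markers fell (12 of 14 lower, 7 at p under 0.05, 6 adjusted over the list alone; median -0.97; camera adjusted p = 4.63e-10, and adjusted p = 0.143 with an estimated correlation). Klk1, of the same list, was at 3.67 ± 1.82 and 0.0649 ± 0.0880 CPM. Erythroblast markers fell (13 of 15 lower, 9 at p under 0.05, 6 adjusted over the list alone; median -2.51, also with Trim10, which had no reads in treated libraries, at its bound; camera adjusted p = 1.27e-12, and adjusted p = 0.143 with an estimated correlation). Slc4a1, the red cell anion exchanger (chromosome 11, 102348820 to 102365281), was at 6.60 ± 2.21 and 0.108 ± 0.050 CPM (-5.92, SE 0.68, adjusted p = 0.0928). Hbb-bs, a beta globin that may share reads with its near copy Hbb-bt, was at 24.5 ± 23.1 and 3.21 ± 1.49 CPM (-2.94, SE 0.66, and -1.35 without PBS 3). Over the single libraries left out, the erythroblast median ran from -3.16 to -1.70, and among genes of at least 10 CPM its call ended (-0.14, adjusted p = 0.159). Megakaryocyte-erythroid priming fell (18 of 22 lower, 7 at p under 0.05, against 1 higher; 0 adjusted over the list alone; median -0.73; adjusted p = 3.2e-06, and adjusted p = 0.143 with an estimated correlation), with the carbonic anhydrase gene Car1 (-2.04, SE 0.66) and Tspan33 (-1.48, SE 0.35) its members of smallest p. Among genes of at least 10 CPM this call ended too (-0.21, adjusted p = 0.206). Platelet and megakaryocyte markers fell (10 of 12 lower, 1 at p under 0.05 and 1 adjusted over the list alone; median -0.60; adjusted p = 0.00788, and adjusted p = 0.357 with an estimated correlation), with Thbs1 at -3.31 (SE 0.77) and Tubb1 at -1.18 (SE 0.53). Without PBS 3 that call ended (0.036, adjusted p = 0.336), and without PBS 2 the median was -1.17. Stromal and endothelial markers fell (9 of 11 lower; 2 lower and 1 higher at p under 0.05, 1 and 1 adjusted over the list alone; median -0.75; adjusted p = 0.011, and adjusted p = 0.357 with an estimated correlation), although Pdgfrb was higher by 1.01 (SE 0.23) and Stab2 lower (-3.56, SE 0.84). Their call ended without MTP10-HDL 2 (-0.52, adjusted p = 0.146) and among genes of at least 10 CPM (-0.04, adjusted p = 0.527), and the median was -2.06 without MTP10-HDL 3.

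Immunoglobulin and MHC class II genes were lower beside these, in the MPP libraries with the smaller immunoglobulin shares. Of the 10 lower genes of smallest p with a mean of at least 10 CPM, 8 were immunoglobulin variable genes, whose reads are hard to assign among near-identical family members. Igkv4-55 was at 220.1 ± 93.8 and 16.4 ± 4.26 CPM (log2 fold change -3.75, SE 0.35) and Igkv14-126, the most abundant, at 4336 ± 1509 and 1029 ± 261 CPM (-2.08, SE 0.33). Igkv17-127 (-3.92, SE 0.41), Igkv8-30 (-3.52, SE 0.43), Ighv1-9 (-3.08, SE 0.33), Ighv1-7 (-3.23, SE 0.45), Ighv1-80 (-2.92, SE 0.41) and Ighv2-2 (-4.22, SE 0.65) were lower too, and so was Abcg3 (-1.38, SE 0.21). B cell markers fell (10 of 16 lower, 5 at p under 0.05, 2 adjusted over the list alone; median -0.57; camera adjusted p = 0.00100, and adjusted p = 0.357 with an estimated correlation). Ms4a1, which encodes CD20, was at 30.0 ± 24.5 and 1.75 ± 0.933 CPM (-4.11, SE 0.68), and Fcrla stood at -1.45 (SE 0.31). The B cell call ended without PBS 2, the library with the highest immunoglobulin share, 12.5% with a 95% Wilson interval of 12.49% to 12.52% (median -0.05, adjusted p = 0.112). Its median was -0.28 without MTP10-HDL 1 and -1.01 without PBS 3. MHC class II genes fell (8 of 10 lower, 4 at p under 0.05, 3 adjusted over the list alone; median -0.51; adjusted p = 0.00032, and adjusted p = 0.357 with an estimated correlation). Cd74, the invariant chain, was at 534 ± 62.6 and 277 ± 75.9 CPM (-0.95, SE 0.26) and H2-Eb1 was lower by 0.97 (log2 fold change -0.97, SE 0.27). Without PBS 3 the class II call ended (-0.42, adjusted p = 0.149). Monocyte and macrophage markers fell (15 of 19 lower, 6 at p under 0.05, 0 adjusted over the list alone; median -0.79; adjusted p = 8.55e-05, and adjusted p = 0.357 with an estimated correlation), with the heme oxygenase gene Hmox1 at -1.71 (SE 0.45) and Apoe at -0.79 (SE 0.28). Without PBS 3 the monocyte median was -0.49.

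Genes of mitochondrial respiration, ribosome biogenesis and heat shock rose in MPPs, and so did ribosomal protein genes, a sign of RNA quality, by amounts that moved with single libraries. Oxidative phosphorylation rose (50 of 52 higher, 3 at p under 0.05, 0 adjusted over the list alone; median 0.50; camera adjusted p = 1.2e-11, and adjusted p = 0.379 with an estimated correlation), with Cox6a1 at 0.86 (SE 0.34) and Ndufa10 at 0.51 (SE 0.22). Its median was 0.23 without MTP10-HDL 2, 0.32 without PBS 2 and 0.77 without PBS 3. The tricarboxylic acid cycle rose (20 of 22 higher; 1 higher and 1 lower at p under 0.05, 0 adjusted over the list alone; median 0.33; adjusted p = 0.00032, and adjusted p = 0.357 with an estimated correlation), with Idh3g at 0.57 (SE 0.23) and pyruvate carboxylase, Pcx, at -0.97 (SE 0.39); without PBS 2 the call ended (0.24, adjusted p = 0.103). Ribosomal protein genes rose (44 of 46 higher, 0 at p under 0.05 or adjusted over the list alone; median 0.37; adjusted p = 6.69e-05, and adjusted p = 0.601 with an estimated correlation), Rps2 by 0.72 (SE 0.36) and Rps6 by 0.59 (SE 0.37). That call ended without MTP10-HDL 2 (0.014, adjusted p = 0.673) or PBS 2 (0.085, adjusted p = 0.846), and the median was 0.75 without PBS 3. Ribosome biogenesis and MYC targets rose (27 of 33 higher, 1 at p under 0.05, 0 adjusted over the list alone; median 0.23; adjusted p = 0.00212, and adjusted p = 0.357 with an estimated correlation), with the nucleolar gene Npm1 at 0.84 (SE 0.29) and Pa2g4 at 0.45 (SE 0.20). Heat shock genes rose (11 of 16 higher; 4 higher and 1 lower at p under 0.05, 0 adjusted over the list alone; median 0.40; adjusted p = 0.0105, and adjusted p = 0.357 with an estimated correlation), although the 2 of smallest p went apart, the inducible Hspa1b at -1.33 (SE 0.37) and the mitochondrial chaperone Hspe1 at 0.85 (SE 0.28). Without MTP10-HDL 3 (0.43, adjusted p = 0.0668) or PBS 2 (0.33, adjusted p = 0.448) it was not called.

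The interferon list rose in MPPs with a median of 0.22 (28 of 35 higher, 5 at p under 0.05, 0 adjusted over the list alone; camera adjusted p = 0.00032, and adjusted p = 0.357 with an estimated correlation). Ifi44 was at 47.9 ± 7.82 CPM (n = 2) and 72.5 ± 7.73 CPM (n = 3; log2 fold change 0.60, SE 0.22), and the guanylate-binding protein gene Gbp3 was higher by 0.82 (SE 0.28). The call ended without PBS 2 (0.039, adjusted p = 0.716), and without PBS 3 the median was 0.48. Immediate early genes fell (20 of 21 lower, 9 at p under 0.05, 0 adjusted over the list alone; median -1.64; adjusted p = 1.09e-08, and adjusted p = 0.357 with an estimated correlation), a list that stands for sample handling, but without PBS 3 the median was 0.25 (adjusted p = 0.716). NF-kB and inflammation genes fell (19 of 27 lower, 4 at p under 0.05, 0 adjusted over the list alone; median -0.34; adjusted p = 0.00623, and adjusted p = 0.357 with an estimated correlation), with the NF-kB inhibitor Tnfaip3 at -1.21 (SE 0.31) and Nfkbiz at -1.42 (SE 0.43). That call ended without PBS 3 (0.012, adjusted p = 0.716) or MTP10-HDL 1 (-0.24, adjusted p = 0.0598). Quiescence genes fell (17 of 23 lower, 4 at p under 0.05, 0 adjusted over the list alone; median -0.27; adjusted p = 0.0122, and adjusted p = 0.357 with an estimated correlation), with the antiproliferative Btg2 at -0.70 (SE 0.23) and Klf6 at -1.88 (SE 0.65; 0.11 without PBS 3), and the median was -0.089 without PBS 3. Both Btg2 and Klf6 are also on the immediate early list, which stands for sample handling, so they are no separate sign of quiescence. Cholesterol synthesis genes fell (16 of 24 lower, 3 at p under 0.05, 1 adjusted over the list alone; median -0.17; adjusted p = 0.0282, and adjusted p = 0.357 with an estimated correlation). Insig1, a gene of sterol feedback, was lower by 0.64 (log2 fold change -0.64, SE 0.21). This call was lost without MTP10-HDL 3 (-0.11, adjusted p = 0.0863), PBS 2 (-0.18, 0.103) or PBS 3 (-0.11, 0.137). With replicate number as a block, quiescence, cholesterol synthesis, NF-kB and heat shock were not called (adjusted p from 0.103 to 0.119).

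No call was made in MPPs for myeloid priming (median 0.00; 13 of 25 higher; 4 higher and 1 lower at p under 0.05, 1 and 1 adjusted over the list alone; camera adjusted p = 0.282) or glycolysis (0.10, 0.0851). Mature neutrophil markers had a median of 0.22 and a mean of 0.20 against a downward camera test (adjusted p = 0.815) and a score difference of -0.30; without MTP10-HDL 3 they were called downward (-1.23, adjusted p = 4.18e-13). Pattern recognition and cytokine receptors (median 0.03, mean -0.05, camera upward, 0.505) and adhesion and homing (0.03, mean -0.01, camera upward, 0.403) were not called. The same held for MHC class I (0.15, adjusted p = 0.0539), the unfolded protein response (-0.18, 0.095), T and NK cell markers (0.58, 0.110), basophil and mast cell markers (-0.54, 0.403) and mitochondrially encoded genes (0.25, 0.195). Calls appeared without MTP10-HDL 1 for myeloid priming (0.12, adjusted p = 0.0365), MHC class I (0.25, 0.0206) and T and NK markers (0.84, 0.0393). Without MTP10-HDL 2 they appeared for glycolysis (0.088, 0.0410), the unfolded protein response (-0.23, 0.0125) and mitochondrially encoded genes (0.49, 0.00111). MHC class I was called also without MTP10-HDL 3 (0.27, 0.0152) or PBS 3 (0.31, 0.0175), the unfolded protein response without PBS 3 (-0.15, 0.0370), and T and NK markers without PBS 2 (0.72, 0.0366). With no filter glycolysis (0.12, 0.0320) and MHC class I (0.18, 0.0138) were called. Replicate number as a block brought calls for myeloid priming (0.11, 0.0369) and MHC class I (0.23, 0.0253), and a mean of 10 CPM for the unfolded protein response (-0.18, 0.0383). Nod2 was at 5.87 ± 0.704 and 3.99 ± 0.851 CPM (-0.56, SE 0.41), Ripk2 at 0.09 (SE 0.30), Il1r1 at 0.61 (SE 0.23), Flt3 at 0.30 (SE 0.21), Mpo at 0.26 (SE 0.21) and Spi1 at 0.003 (SE 0.33). Csf2rb (-0.11, SE 0.22), Cebpa (-0.14, SE 0.34), Hk2 (-0.16, SE 0.20) and Gata1 (-0.75, SE 0.54) had negative values that did not pass.

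Gene tests in MPPs rested on 2 and 3 libraries. Of 15449 genes 0 passed FDR 0.05 in edgeR and 963 had an unadjusted p under 0.05 (335 higher, 628 lower), against 772 by chance. DESeq2 called 163 genes (20 higher, 143 lower), voom 28 (2 higher, 26 lower), edgeR with no filter 345 (49 higher, 296 lower) and with replicate number as a block 59 (2 higher, 57 lower). With the block, MTP10-HDL 1 has no PBS library of its number and does not enter the treatment effect. Fitted jointly with the HSC libraries 11 genes passed, all lower, and without PBS 3 the count was 17, all lower. At FDR 0.1 the edgeR count was 9, all lower: Siglech, Slc4a1 and 7 immunoglobulin variable genes, of which Igkv1-132, Ighv13-2 and Igkv1-133, named after their values were seen, had no reads in treated libraries and 9.63, 12.1 and 10.2 CPM in PBS. Of the lists, 22 passed camera (9 up, 13 down), 0 with an estimated correlation, where the smallest adjusted p was 0.143, and 0 by the exact score test, which cannot go below 0.1 here.

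Responses of the 2 cell types were then set against each other, the question being whether stem cells and progenitors answer alike. Cell type went together with library kit and depth, and the injection schedule is not given for HSCs. A difference in response therefore cannot be told apart from an effect of these. In the joint fit 1 of 24470 genes differed in response at FDR 0.05, the unclassified locus Gm43360, named after its value was seen (adjusted p = 0.0368). It had 13.8 ± 3.98 and 9.54 ± 4.73 CPM in HSCs, 28 reads in PBS MPPs and none in treated MPPs, where it was at least 28.8-fold lower with a floor of 3 counts over the group. In all, 945 genes had an unadjusted p under 0.05. Among genes of at least 10 CPM in both cell types the count was 0, and by voom 1. Il7r differed by 2.32 (SE 0.71) but did not pass over all genes (adjusted p = 0.913), and among the named genes its adjusted p was 0.219. By camera 17 lists differed, and with an estimated correlation 0 did, the smallest adjusted p being 0.343. Lymphoid priming, lower in HSCs and higher in MPPs with a median difference of 0.64, was the 1 list with an exact permutation p under 0.05 for its score (p = 0.0427 over 17160 arrangements, Benjamini-Hochberg 0.608).

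In both cell types 11 lists were called, 10 of them in the same direction (interferon response, oxidative phosphorylation, tricarboxylic acid cycle, S phase and ribosomal proteins up; erythroblast, megakaryocyte-erythroid, B cell, dendritic and immediate early lists down; ribosomal protein and immediate early genes stand for RNA quality) and 1, lymphoid priming, in opposite directions. A further 8 lists were called in HSCs alone and 11 in MPPs alone, which does not show by itself that the responses differ. Across 13593 genes the fold changes of the cell types correlated with Pearson r = 0.377 and Spearman rho = 0.298, and genes are not independent replicates. Among 10 regroupings of the MPP libraries the real one gave the highest r, with 0.186 the highest other.

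**Figure D3:**
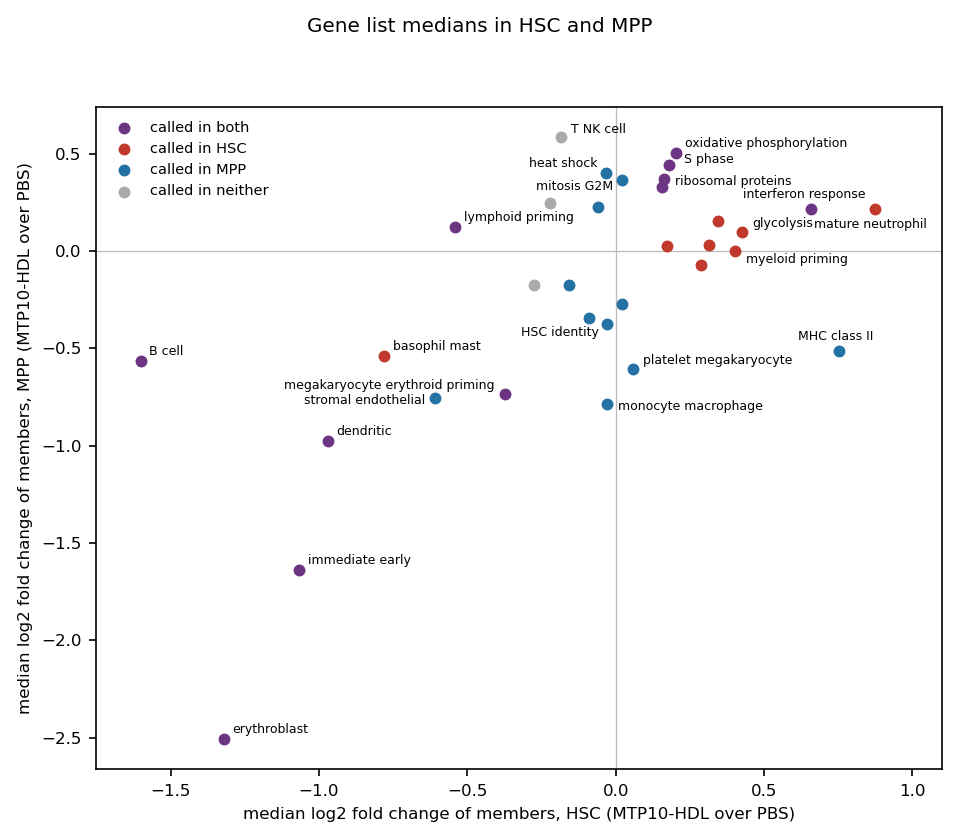
Median log2 fold change (MTP10-HDL over PBS) of each of 33 gene lists in HSCs (horizontal) and MPPs (vertical), coloured by where camera called the list. Erythroblast markers sit lowest in MPPs (-1.32 and -2.51), and lymphoid priming is the list called in both with opposite signs (-0.54 and 0.13).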

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

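The tests within technical groups, those of myeloid scores, globins and B cell markers were chosen after the results were seen, while the plasma cell test and the regroupings of libraries were set out before. Single libraries that stand far from the others of their group are given first; Dixon's test was run on 204 groups and singled out 13, where chance singles out about 1 in 20 groups, 10.2 here.

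PBS 2 stood apart among HSC libraries in its immunoglobulin share, 19.8% of counts, and in Igf2r, 83.5 CPM. PBS 1 was high in mitochondrially encoded genes (score 0.87) and in Plac8 (141 CPM). PBS 4 was low in T and NK cell markers (score -0.85) and Cebpa (3.51 CPM), PBS 5 low in Ndufv1 (28.9 CPM), and PBS 6 high in Irf9 (89.9 CPM). MTP10-HDL 1 was low in S phase (score -0.29), mitosis (-0.67) and ribosomal protein genes (-0.24) and high in NF-kB and inflammation genes (0.69). MTP10-HDL 6 was high in Tap1 (181 CPM).

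The responses of MPPs and HSCs differed by camera for 17 lists, none of which passed with an estimated correlation or by the exact score test after adjustment. Library kit and depth differ between the cell types and cannot be told apart from cell type in these differences. As the median of MPP minus HSC log2 fold changes, the lists higher in MPPs were B cell markers (0.82), lymphoid priming (0.64), mitochondrially encoded genes (0.42), mitosis (0.41), heat shock (0.40), S phase (0.32), oxidative phosphorylation (0.29), ribosomal proteins (0.25) and ribosome biogenesis (0.23). Lower in MPPs were erythroblast markers (-0.92), stromal markers (-0.75), platelet markers (-0.65), neutrophil markers (-0.63), the interferon response (-0.42), HSC identity (-0.37), glycolysis (-0.24) and immediate early genes (-0.18). The locus Gm43360 was the 1 gene past the threshold, and its fitted difference of -6.0 is no measured size, since treated MPPs had no reads of it.

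The interferon genes higher in HSCs were weighed against mature myeloid cells in the sorted samples, since MTP10-HDL 1 had the highest score of both. With the monocyte and neutrophil scores of each library as covariates the interferon difference was 0.675 (SE 0.145), against 0.659 (SE 0.173) without them, so a linear share of such cells does not account for it. Nor do the technical groups, since the difference was above 0 in each and the exact permutation within them gave p = 0.00278, the smallest of 360 arrangements. The list and its camera test were fixed in advance, but the score, covariate and technical group tests were chosen later on the same libraries. A response of the HSCs to treatment remains a hypothesis, and the lists called in other regroupings weaken the camera p. The interferon list was called in 65 of 100 regroupings, upward in some and downward in others, and in 2, the real one included, with as small a p. The other of these set MTP10-HDL 1, 2, 3, 5 and 6 with PBS 7 against the remaining libraries, and so kept most of the treated libraries together.

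Erythroid genes lower with MTP10-HDL in both cell types were weighed against erythroblasts in the sorted PBS samples. Erythroblasts make more globin than any other message, yet the 4 adult globin genes together stayed below Ermap in 6 of 7 PBS HSC libraries (48.3 ± 43.3 CPM against 126 ± 40.3 CPM, SD, n = 7), PBS 3 being the exception. This cannot decide on erythroblasts in HSCs, since globin genes have near copies and the handling of reads with several matches is not given. Among treated HSC libraries globins lay above Ermap in MTP10-HDL 1 (23.6 against 15.6 CPM) and MTP10-HDL 3 (42.2 against 38.5 CPM), and below it in the others. Here CPM are scaled to the counts of all genes rather than of those kept by the filter, so Ermap differs slightly from its value in Results. In PBS MPPs the globins stayed below Ermap in 0 of 2 libraries, and Hbb-bs was lower with treatment (-2.94, SE 0.66; -1.35 without PBS 3) while Hbb-bt was not (0.05, SE 0.36), so erythroblasts cannot be told apart there from the treatment. Technical groups of HSC libraries are argued against by a fall in each of them (exact p = 0.0111 within groups). Fewer erythroid-primed cells inside the HSC gate may be part of the pattern and were not tested.

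Immunoglobulin transcripts were lower with MTP10-HDL by -0.80 (log2 share, exact p = 0.44) in HSCs and by -1.26 (exact p = 0.1) in MPPs. Across the 13 HSC libraries the share went with the score of 15 plasma cell markers (Spearman rho = 0.907, permutation p = 6.0e-05; Pearson r = 0.947, and 0.893 without PBS 1 and PBS 2; Benjamini-Hochberg 9.0e-05 over 3 relations), as plasma cells or their RNA in the samples would give, and with the unfolded protein response list (rho = 0.907, r = 0.938, and 0.873 without those libraries), which shares 3 of the 15 markers; the B cell list shares 0. For B cell markers rho was 0.588 (permutation p = 0.0386), and r went from 0.704 to 0.374 without the same libraries, so that relation rests on them and B cells stay open. With the technical groups held fixed the HSC difference was -1.02, no smaller than without them, but its sign varied between groups (exact p = 0.206 within groups), so the part of these groups stays open. A sort on lineage markers should remove B cells, plasma cells carry few of them, and no biological explanation was tested.

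For the number of genes past FDR 0.05, regrouping the HSC libraries decides nothing about chance: the real count was 0, which all 100 regroupings reach by definition. Of these, 4 called any gene, and the highest other gave 39, a count that a structure of the samples other than treatment could give. That regrouping set MTP10-HDL 1 and 2 and PBS 1, 2, 3 and 5 against the other libraries, mostly low replicate numbers against higher ones. No such structure was tested for this count. Chance cannot be excluded for the number of lists called: 9 of 100 regroupings gave as many as the real 19, and the highest other gave 24, with a median of 14. For the correlation of HSC and MPP fold changes 1 of 100 regroupings, the real one, reached the Pearson r of 0.377, and the highest other was 0.322. That argues against chance for Pearson r, the measure of the test set out before. As 6 of 100 reached the real Spearman rho, the answer depends on the coefficient and chance is not excluded.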

How the results depend on the processing

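The fits without pairs of libraries, with a technical group term, with an immunoglobulin share covariate, without immunoglobulin genes or with thinned counts, and the score tests, were chosen after the data were seen; the other settings were fixed before. Under all settings run, 21 of 33 lists in HSCs and 23 of 33 in MPPs kept the sign of their median, as did 57 of 62 named genes in HSCs and 62 of 67 in MPPs. Values were then counted over all pairs of a list or gene with a setting. List values stayed on their side of the threshold with the same sign in 658 such pairs in HSCs and 323 in MPPs. They turned in 68 and 20, lost the call in 48 and 67 and gained it in 18 and 18. The MPP losses include all 22 called lists under the exact score test, which cannot pass there, and again under camera with an estimated correlation. Gene values turned in 30 pairs in HSCs and 15 in MPPs. Where a result below moved or turned, the cause was not tested unless one is named. On simulated data of the MPP design edgeR recovered 10% of changes of log2 size 1.

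In HSCs 0 genes passed in edgeR, with 1469 at an unadjusted p under 0.05. The count was 44 without a filter and 104 by DESeq2, both of which test more genes and move the median of all genes, and 0 by voom; leaving out single libraries it ran from 0 to 1, the 1 without MTP10-HDL 4. Of 19 lists called, 1 was called with an estimated correlation and 3 by scores. In MPPs 0 genes passed in edgeR, with 963 at an unadjusted p under 0.05, against 345 without a filter, 163 by DESeq2, 28 by voom, 11 in the joint fit, 9 at FDR 0.1, 1 with thinned counts and 0 to 17 with single libraries left out. With replicate number as a block, although numbers did not pair the MPP libraries, the MPP count was 59. In the block fits MPP MTP10-HDL 1 and HSC PBS 7 have no partner of their number and do not enter the treatment effect. Of 22 MPP lists, 0 were called with an estimated correlation and 0 by scores, which cannot pass here. The 1 gene differing between cell types fell to 0 at a mean of 10 CPM, which leaves it out, and the 17 lists to 0 with an estimated correlation and 0 by scores. The correlation of fold changes was 0.488 at a mean of 10 CPM.

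Medians and fold changes near 0 turned sign as follows, in log2 units. Without a filter: HSC identity 0.026 (called upward, adjusted p = 0.0308), ribosome biogenesis 0.0086, heat shock 0.032 and Procr 0.068 in HSCs. At a mean of 10 CPM: mitosis -0.039, NF-kB 0.027, T and NK markers 0.042, platelet markers -0.042 and Flt3 -0.050 in HSCs, and myeloid priming -0.012, adhesion -0.0031 and Spi1 -0.059 in MPPs. By voom: Nod2 -0.56, Flt3 -0.071, Gata1 0.13 and Cebpa -0.0083 in HSCs, and Ripk2 -0.082 and Spi1 -0.15 in MPPs. With the replicate block: HSC identity 0.072, mitosis -0.053, quiescence -0.0087, MHC class II -0.095, Procr 0.034 and Flt3 -0.054 in HSCs. In the joint fit: Procr 0.020 in HSCs. Without immunoglobulin genes: Procr 0.0053 in HSCs, and myeloid priming and Spi1 -0.021 in MPPs. Without HSC PBS 5 and 7: mitosis -0.023, quiescence -0.050, heat shock 0.015, platelet markers -0.10, Procr 0.092 and Flt3 -0.032. Without HSC PBS 1 and MTP10-HDL 1: HSC identity 0.034, ribosome biogenesis 0.051, heat shock 0.12, MHC class II -0.20, Procr 0.041 and Gata1 0.16. With the technical group term: HSC identity 0.012, platelet markers -0.042 and Procr 0.018. With the immunoglobulin share as covariate: cholesterol synthesis 0.0067, unfolded protein response 0.11 and monocyte markers 0.56. As score differences: HSC identity 0.044, mitosis -0.030, quiescence -0.081 and platelet markers -0.16 in HSCs, and receptors -0.077, adhesion -0.027 and neutrophil markers -0.30 in MPPs. With DESeq2 size factors, myeloid priming and Spi1 stood at -0.018 in MPPs, by DESeq2 Spi1 at -0.015, and with thinned counts replication histones at 0.045.

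Leaving out single HSC libraries, the values that turned sign ran as follows: HSC identity -0.067 to 0.073, ribosome biogenesis -0.084 to 0.00098, heat shock -0.12 to 0.048, MHC class II -0.42 to 0.92, platelet markers -0.078 to 0.22, quiescence -0.021 to 0.12, NF-kB -0.19 to 0.093, monocyte markers -1.26 to 0.54, mitosis -0.031 to 0.14, T and NK markers -0.42 to 0.029 and the unfolded protein response -0.42 to 0.063. Among genes these were Procr -0.053 to 0.075, Flt3 -0.081 to 0.16, Cebpa -0.046 to 0.34 and Gata1 -0.37 to 0.014. In MPPs they were replication histones -1.09 to 0.39, receptors -0.026 to 0.11, neutrophil markers -1.23 to 0.65, the unfolded protein response -0.23 to 0.051, adhesion -0.0080 to 0.11, NF-kB -0.51 to 0.012, immediate early genes -2.43 to 0.25, platelet markers -1.17 to 0.036 and basophil markers -0.63 to 0.17. Among MPP genes they were Cebpa -0.54 to 0.043, Ripk2 -0.15 to 0.37, Spi1 -0.39 to 0.52, Csf2rb -0.34 to 0.16 and Klf6 -2.70 to 0.11. Lists that were not called could also move and keep their sign. In HSCs stromal and endothelial markers ran from -0.80 to -0.15, mitochondrially encoded genes from -0.27 to -0.0067 and cholesterol synthesis from -0.21 to -0.022. Other gene values kept their sign but had one end of their range more than 2 times the other. In HSCs these were Plac8 0.38 to 0.78, Rag1 -3.21 to -1.25, Chil3 0.74 to 1.81, H2bc4 -0.92 to -0.41, Nod2 0.11 to 0.56 and Ripk2 -0.47 to -0.12. So were Mpo 0.021 to 0.71, Mki67 -0.27 to -0.13, Cdk1 0.044 to 0.25, Hk2 0.084 to 0.32, Il1r1 -0.36 to -0.12, Csf2rb 0.37 to 0.82 and Spi1 0.24 to 0.54. In MPPs they were Btg2 -0.97 to -0.39, Cox6a1 0.49 to 1.06, Idh3g 0.36 to 0.80, Gbp3 0.51 to 1.19, Tnfaip3 -1.57 to -0.75, Nfkbiz -1.97 to -0.54 and Rps2 0.35 to 1.00. Also there, they were Rps6 0.21 to 0.92, Apoe -1.04 to -0.49, Hbb-bs -3.69 to -1.35, Tubb1 -1.92 to -0.84, Mpo 0.12 to 0.40, Gata1 -1.04 to -0.49, Mki67 0.031 to 0.55 and Hk2 -0.24 to -0.075. Without an MPP PBS library a single PBS library is left, which is assumed to vary like the treated ones.

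List calls also came and went in settings other than single libraries left out. In HSCs the replication histone call ended with the replicate block (0.14, adjusted p = 0.599), at a mean of 10 CPM (0.22, 0.147) and without PBS 5 and 7 (0.062, 0.567). Calls were gained with the replicate block for monocyte markers (-0.37, adjusted p = 2.32e-06) and the unfolded protein response (-0.27, 0.00429). The latter was called at a mean of 10 CPM (-0.26, 0.0317), without PBS 5 and 7 (-0.42, 0.000185) and with the technical group term (-0.31, 0.00975). MHC class II was called with no filter (0.80, 0.0125). Without PBS 5 and 7, ribosomal proteins (0.012, 0.672) and the tricarboxylic acid cycle (0.086, 0.0760) were no longer called, while NF-kB was (-0.085, 0.0496). Without PBS 1 and MTP10-HDL 1, mitosis (0.17, 0.00970) and NF-kB (-0.16, 0.0346) were called and receptors were not (0.14, 0.115). In MPPs calls were gained with no filter for glycolysis (0.12, 0.0320) and MHC class I (0.18, 0.0138). The replicate block gained myeloid priming (0.11, 0.0369) and MHC class I (0.23, 0.0253). The unfolded protein response was called at a mean of 10 CPM (-0.18, 0.0383) and without immunoglobulin genes (-0.20, 0.0486), and T and NK markers with thinned counts (0.66, 0.0226).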

Other observations

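The genes in these first paragraphs were chosen after their values were seen, as were the settings named with them. Members of the lymphoid priming list went both ways in MPPs. Higher with MTP10-HDL were several members: Dntt, the polymerase that adds bases at antigen receptor joints, was at 586 ± 147 CPM (SD, n = 2) with PBS and 1354 ± 276 CPM (n = 3) with MTP10-HDL (log2 fold change 1.21, SE 0.29), and the chromatin organiser Satb1 at 148 and 264 ± 39.6 CPM (0.83, SE 0.21), beside Il7r and Rag2. Other members were lower: Ikzf3 by 1.92 (log2 fold change -1.92, SE 0.55), Ccr9 (-0.996, SE 0.27), Ly6d (-0.80, SE 0.30) and Lax1 (-0.65, SE 0.21). Of these, Ly6d did not pass adjusted over the list alone (0.0634), and none passed over all genes. Myeloid priming genes also went both ways in MPPs, with Plac8 (1.32, SE 0.42), Cst7 (1.47, SE 0.30), Cebpd (1.14, SE 0.42) and the granule protease gene Ctsg (0.88, SE 0.28) higher and the monocyte-lineage gene Ly6c2 lower (-0.95, SE 0.19).

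The homing receptor gene Cxcr4 was higher in both cell types, by 0.54 (SE 0.18) in HSCs and 0.93 (SE 0.21) in MPPs, and so was Selp, by 1.07 (SE 0.28) and 1.06 (SE 0.31). Among stem cell genes in MPPs the transcription factor gene Hlf was at 536 ± 82.7 and 286 ± 58.4 CPM (-0.91, SE 0.24). In HSCs the interferon genes included Isg15 (1.53, SE 0.45), Irf7 (1.16, SE 0.37), Oasl2 (0.91, SE 0.21) and Rtp4 (0.98, SE 0.24). Glycolytic genes included Ldha, which makes lactate, at 307 ± 84.2 CPM (n = 7) and 487 ± 114 CPM (n = 6; 0.67, SE 0.19), and Pgk1 (0.69, SE 0.21).

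Libraries of the same replicate number were mostly not alike pair by pair across the treatments. Correlations of centred expression between libraries of the same number ran from -0.19 to 0.19 over 6 HSC pairs, of which 2 exceeded 0.1, and were -0.17 and -0.03 in MPPs. The first principal component of HSC libraries held 27.4% of the variance and ran from PBS 5 (-86.6) and PBS 7 (-68.3) to the libraries with few detected genes, MTP10-HDL 3 (75.8) and PBS 4 (88.1), rather than from PBS to MTP10-HDL. The second component held 14.2% and followed replicate number in both treatments. Libraries numbered 1 to 3 lay above 0, from 3.0 (MTP10-HDL 3) to 61.0 (PBS 1). Those numbered 4 and higher lay below 0, from -55.4 (PBS 4) to -5.1 (MTP10-HDL 4). Replicate numbers thus went with a shared structure of the HSC libraries, whose cause was not tested. The plasma cell score differed by -0.38 in HSCs (exact permutation p = 0.552) and by -0.67 in MPPs (exact p = 0.2, with 0.1 the smallest possible).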
